A study of Mus musculus with 6 samples.

How the data were processed

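Small RNA libraries were prepared from Trizol-extracted total RNA with the TruSeq Small RNA kit, per the labels' protocols. They came from the dorsal striatum, isolated by cryosection, of C57BL/6N mice aged 7 weeks. Nicotine (0.5 mg/kg) was injected once daily for 3 days, mecamylamine (3.0 mg/kg) followed 24 hours after the last nicotine injection, and tissue was taken 1 week after the last injection. The labels put 3 libraries in each group and speak of 3 mice treated with nicotine, and each library was taken as 1 mouse. Where this does not hold, the p-values measure only the spread between samples.

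The authors deposited one table of normalized signal, in which each value is a miRNA's read count divided by a size factor of its library. The submitters' processing notes name the mouse build mm9 and DESeq2, with no version or role. The aligner, the miRNA annotation release, the treatment of reads that map to several miRNAs and the filters are not given in the sources used here. Reads shared by near-identical miRNAs may therefore be split or counted for both. Within each library all values were whole multiples of one step (100% within 0.01 of a step). Dividing by the step gave an estimate of the reads, which holds if a step is 1 read. It was used to describe depth, to compare libraries of one group and as depth in a model of the epithelial list below. No miRNA was called from it. The smallest positive value was 4 steps in control 2 and 5 steps in the other libraries, so a listed 0 may hide smaller values. At 100 reads the counting error alone is 10%, and PCR copies add to it since the reads carry no molecular identifiers.

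The test fixed before the data were examined was a count test for raw counts, with limma as its stated replacement for normalized values. The replacement was used, and no count test was run, since no value of 1 step was listed to show that a step is 1 read. Values were taken as log2(value + 1), and miRNAs with a value of at least 10 in at least 3 libraries were kept (699 of 756, comprising 5p arms, 3p arms and names without an arm; 57 were not tested). limma 3.58.1 in R 4.3.3 fitted the group difference with empirical Bayes moderation and a trend of variance on level, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low miRNAs.

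Lists of miRNAs for cell types, neuronal functions, families and clusters (18 lists) were fixed before the data were examined, and those with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Arm balance was tested with limma on log2((5p + 1)/(3p + 1)), without a trend of variance on level. The named miRNAs were fixed by rule before the data were examined. They are the 10 with the smallest p in each direction among those past the threshold, the 5 most abundant, the most abundant member and the member with the smallest p of each list, and the 3 arm ratios with the smallest p. Names outside the rule are said to be chosen after their values were seen.

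The code was tested on simulated data with the spread of these 699 miRNAs in 20 runs of the withdrawal comparison. It called 39.4% of miRNAs changed by 1.1-fold, 65.2% at 1.2-fold, 81.8% at 1.5-fold and 93.6% at 2-fold, and 3.74% of calls were unchanged miRNAs. In each run 200 miRNAs were changed, and independent errors were drawn with the variances of the fit with the trend. The rates hold under that fit and cannot show whether its trend is right, on which the calls below depend. They also rest on the 200 changed miRNAs, more than the 46 called in the data. The adjusted threshold is easier to pass when more miRNAs change, so the rates may be too high here. The median residual SD on the log2 scale was 0.31 for miRNAs under 100 normalized reads and 0.04 for those of at least 10000. Libraries of one group differed by more than sampling noise (chi-square per degree of freedom from 21.6 to 162, on the reads estimated above), so none was a copy of another.

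The alternatives were other pseudocounts (0.5 and 5), no filter and a filter of 50, rescaling by median ratios, limma without a trend, the most abundant miRNA left out, the replicate number as a block, and each library left out in turn. Equal library totals, quantile normalization, miRNAs above 0 in every library and a robust variance prior were added after seeing the data. Gene neighbours were taken from a RefSeq table of the GRCm38 assembly, used for names and neighbours alone since the notes name another build, and no coordinates are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.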

Results

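Mature microRNAs (miRNAs), short RNAs that repress messenger RNAs by base pairing, were sequenced from the dorsal striatum of C57BL/6N mice, the part of the basal ganglia that serves habit learning and action selection. The question was how the miRNA profile of this region differed 1 week after precipitated nicotine withdrawal. In the nicotine withdrawal group (n = 3), nicotine was given at 0.5 mg/kg on each of 3 days, and withdrawal was precipitated with 3.0 mg/kg mecamylamine, an antagonist of nicotinic acetylcholine receptors. The saline control group (n = 3) received neither drug, so the comparison covers nicotine and mecamylamine together. The table held 756 mature miRNAs in 6 libraries, as read counts divided by a size factor per library. The values lay on whole multiples of a step in each library, and if a step is 1 read the totals were estimated to lie between 40111870 and 50480767 per control library and between 44529730 and 53262896 per withdrawal library. Below, values are normalized reads as mean ± SD (n = 3 per group), and log2 fold changes (withdrawal over saline) are given ± SE on the log2(value + 1) scale.

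The profile was dominated by a few miRNAs. miR-127-3p, from the imprinted Dlk1-Dio3 cluster, took 20.9 ± 0.234% of normalized reads in controls and 20.2 ± 0.754% in withdrawal. The 5 most abundant miRNAs (miR-127-3p, miR-181a-5p, miR-30a-5p, miR-26a-5p and miR-22-3p) together took 47.1 ± 0.276% and 46.3 ± 0.128%. Of these, miR-22-3p was lower in withdrawal and miR-30a-5p was higher (log2 fold change 0.11 ± 0.03, limma, Benjamini-Hochberg adjusted p = 0.0468). The miR-30a-5p call was marginal and passed in 9 of 18 alternative settings. The other three did not pass the test, with log2 fold changes of -0.08 ± 0.03 for miR-127-3p, -0.03 ± 0.05 for miR-181a-5p and -0.08 ± 0.03 for miR-26a-5p. The first principal component held 33.3% of the variance and separated the groups, with controls between -4.30 and -3.13 and withdrawal libraries between 2.52 and 5.60. It was computed on log2 values not scaled by miRNA. These included miR-6238, listed at 0 in each withdrawal library, which adds to the separation.

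Nicotine withdrawal was accompanied by small changes in 46 of the 699 miRNAs tested, 21 of them higher and 25 lower. These calls depend on the fit: limma without the trend of variance on level called 0 (smallest adjusted p = 0.141), and 13 passed without control 2. The largest rise was that of miR-141-3p, an epithelial miRNA of the miR-200 family, from 105 ± 13.9 to 172 ± 22.9 normalized reads (log2 fold change 0.71 ± 0.13, limma, adjusted p = 0.00759). miR-183-5p and miR-182-5p, from a cluster known from sensory organs, rose from 358 ± 23.4 to 492.5 ± 13.9 (0.46 ± 0.07) and from 3733 ± 109 to 4875 ± 525 (0.38 ± 0.06), each at limma adjusted p = 0.00673. miR-10b-5p, encoded in a Hox cluster, rose from 554 ± 19.2 to 727 ± 91.99 (0.38 ± 0.08, limma adjusted p = 0.0130). Among more abundant miRNAs, miR-146b-5p and miR-146a-5p, known as regulators of inflammatory signalling, rose by 0.24 ± 0.04 and 0.19 ± 0.04, from 72443 ± 1313 to 85981 ± 6747 and from 6522 ± 20.8 to 7444 ± 459.

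The remaining higher miRNAs among those with the smallest p were miR-324-5p (0.20 ± 0.04), miR-344-3p (0.18 ± 0.03), and miR-486a-5p and miR-486b-5p (0.16 ± 0.03 each). With quantile normalization the miR-486 pair stood at 0.12 and 0.09 (limma adjusted p = 0.134 and 0.188). The values of the miR-486 pair differed by at most 0.162% in any library, so the gap between 0.12 and 0.09 comes from that normalization. Both are among the 46, but the pair cannot be counted as separate evidence and its reads may not be assignable to one of them.

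The lower miRNAs included several of the most abundant brain miRNAs. miR-22-3p fell from 2560370 ± 68939 to 2256080 ± 17509 normalized reads (log2 fold change -0.18 ± 0.03, limma, adjusted p = 0.00673). With quantile normalization it stood at -0.06 (limma adjusted p = 0.566), while miR-30a-5p had the mirror value of 0.06 at the same adjusted p. That method fixes the value of each rank, so an exchange of ranks between them sets these values and not the size of the miR-22-3p change. miR-434-3p, from the Dlk1-Dio3 cluster, fell from 1032280 ± 21575 to 874686 ± 78597 (-0.24 ± 0.05). miR-138-5p, a neuronal miRNA known to act on dendritic spine size, fell from 500527 ± 21649 to 422669 ± 32751 (-0.25 ± 0.05). miR-338-3p, an oligodendrocyte miRNA, fell from 87651 ± 3007 to 78261 ± 1419 (-0.16 ± 0.03).

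miR-497a-5p, miR-322-5p and miR-16-5p, which share a seed sequence, fell by 0.38 ± 0.07, 0.21 ± 0.04 and 0.15 ± 0.03 on the log2 scale. With quantile normalization miR-16-5p stood at -0.04 (limma adjusted p = 0.567). miR-3085-3p fell by 0.38 ± 0.08 and miR-485-5p, a synaptic miRNA, by 0.19 ± 0.03. miR-6238 passed the test at 12.5, 82.7 and 10.98 normalized reads in the controls, while it was listed at 0 in each withdrawal library. No fold change is given for it, since the smallest positive value in the libraries was 4 or 5 steps and a listed 0 may cover smaller values.

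**Figure D1:**
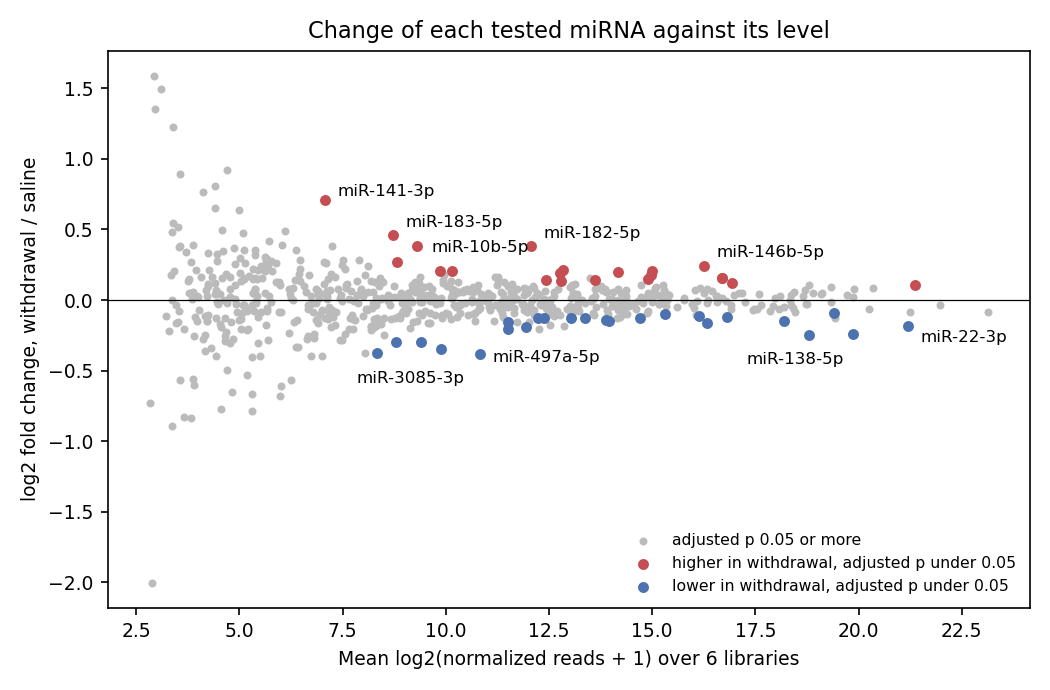
Log2 fold change of each tested miRNA (withdrawal over saline, vertical) against its mean log2(normalized reads + 1) over 6 libraries (horizontal), without miR-6238. Red and blue points are the miRNAs past adjusted p 0.05, higher and lower in withdrawal; miR-141-3p has the largest rise among them, 0.71.

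**Figure D2:**
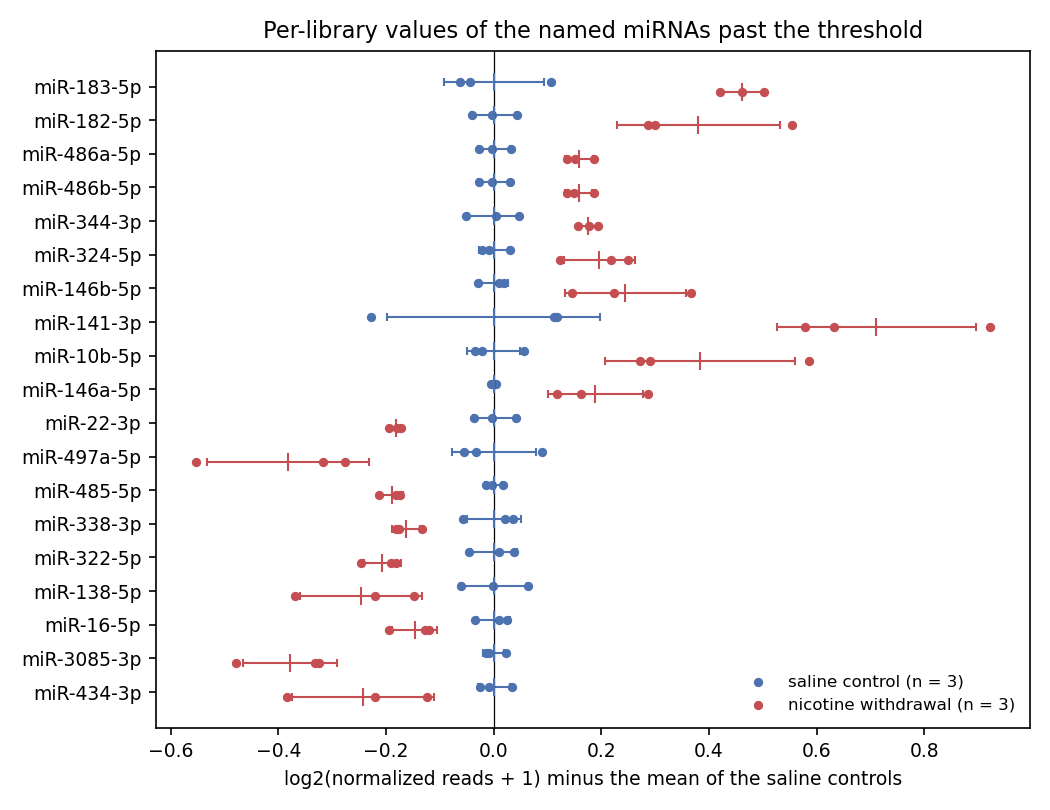
Log2(normalized reads + 1) of each library minus the mean of the 3 saline controls. Drawn are the 10 miRNAs with the smallest p in each direction among those past the threshold, except miR-6238. Points are libraries, ticks are group means and bars are SDs; for every miRNA drawn, the 3 withdrawal libraries lie on one side of the 3 controls.

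The changes were small against the usual fold thresholds. Of the 46 miRNAs, 35 changed by less than 1.2-fold and 44 by less than 1.5-fold, and the 45 above 0 in every library ranged from 1.07-fold to 1.64-fold. The groups did not overlap in any of the 46, nor in 27.6% of all tested miRNAs, where chance gives 10% for 3 against 3. With the values scaled to equal library totals, 61 miRNAs passed, 46 higher and 15 lower, so that 75.4% of calls were higher against 45.7%. With quantile normalization 22 passed, 9 higher and 13 lower, and 13 of these were among the 46. The count was 0 in limma without the trend of variance on level (112 at an unadjusted p under 0.05, 160 with the trend), and fell to 13 without control 2, 22 without control 3 and 21 without withdrawal 2.

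Of the 17 miRNA lists tested, the choroid plexus, ependymal and epithelial list was higher in withdrawal in limma's camera with a preset correlation of 0.01 (adjusted p = 0.00122). This call was lost when camera estimated the correlation (adjusted p = 0.290), and fry gave an adjusted p = 0.0329. The estimated value was 0.012, close to the preset, so a stronger correlation among members does not account for the loss. The unadjusted camera p was 7.2e-05 with the preset and 0.017 with the estimate. When it estimates the correlation, camera also takes fewer degrees of freedom, so the loss does not show that the members moved less. Its 19 measured members had a mean log2 fold change of 0.18 and a median of 0.08, and 15 of them had positive values. miR-182-5p, miR-183-5p and miR-141-3p passed the test over all miRNAs, and 5 members passed adjusted over the list alone. The most abundant member, miR-204-5p of the choroid plexus, stood at 87931 ± 1967 and 92113 ± 1318 normalized reads (log2 fold change 0.07 ± 0.03, limma, adjusted p = 0.156). The 3 members that passed over all miRNAs are known from epithelia and sensory organs.

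**Figure D3:**
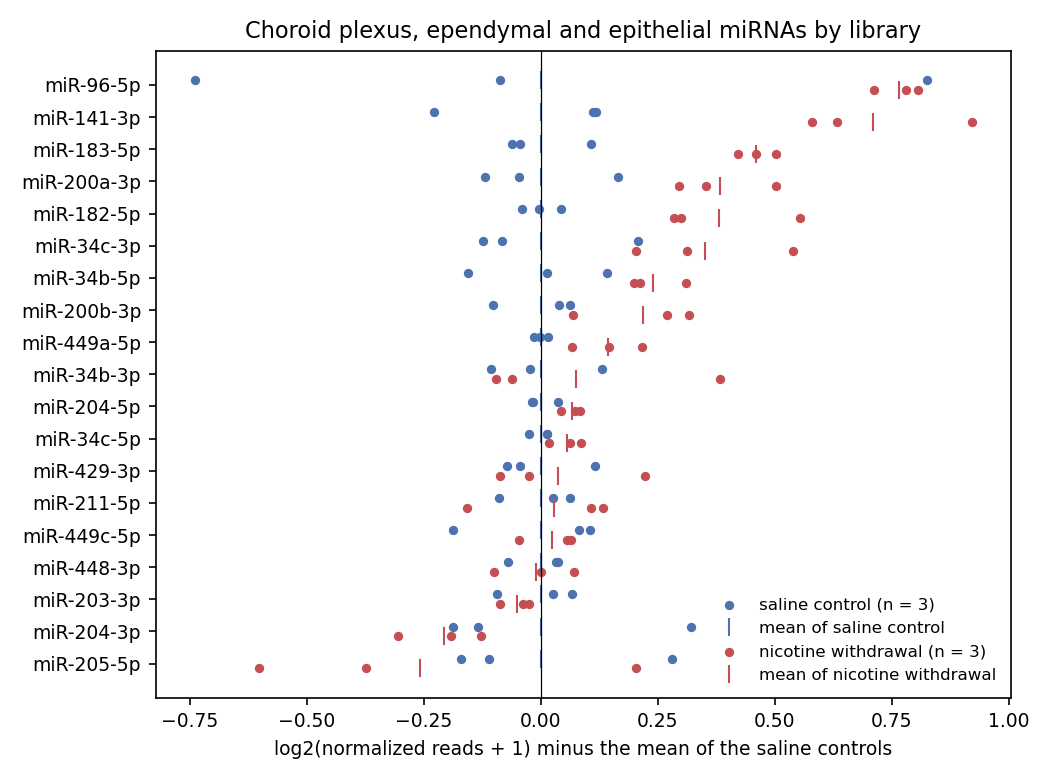
Log2(normalized reads + 1) of each library minus the mean of the saline controls, for the 19 measured members of the choroid plexus, ependymal and epithelial list. Points are libraries and ticks are group means; miR-141-3p, miR-183-5p and miR-182-5p stand clear of the controls in all 3 withdrawal libraries.

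Other cell type lists did not pass as lists, though single members did. In the microglia and leukocyte list, 2 of 8 members rose (miR-146a-5p and miR-146b-5p) and miR-150-5p, a lymphocyte miRNA, fell by 0.13 ± 0.03 (camera adjusted p = 0.807). In the erythrocyte list, the miR-486 pair rose, a call lost with quantile normalization, and 5 of 7 members did not pass (camera adjusted p = 0.118). Of its 7 members 6 had positive values, and 3 were higher adjusted over the list alone, the third being miR-451a (0.15 ± 0.05, limma adjusted p = 0.0688 over all miRNAs), named after its value was seen. Both of the miR-486 pair enter these counts and the list test, though they are not separate evidence. Of 6 endothelial and vascular smooth muscle miRNAs, miR-126a-3p, the main endothelial miRNA, fell by 0.10 ± 0.03, while miR-143-3p stood at 0.08 ± 0.03 (limma adjusted p = 0.0347 and 0.141). Of 6 muscle miRNAs, miR-1a-3p rose by 0.27 ± 0.06, and miR-133a-3p stood at 0.00 ± 0.03. Of 5 oligodendrocyte miRNAs, miR-338-3p fell and 4 did not pass. Of 6 pituitary and endocrine miRNAs, miR-7a-5p rose by 0.21 ± 0.05, and miR-212-3p stood at -0.05 ± 0.03. The Hox list had 2 measured members and was not tested as a list, with miR-10b-5p higher and miR-10a-5p at -0.05 ± 0.04. Of these calls, miR-1a-3p passed in 11 of 18 alternative settings, and miR-126a-3p and miR-7a-5p in 12 of 18 each. Adjusted over the list alone, 2 pituitary and endocrine members were higher, and the counts of the microglia, endothelial, muscle, oligodendrocyte and Hox lists were as over all miRNAs.

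In each neuronal list most members did not pass. Of 14 neuron-enriched miRNAs, miR-138-5p fell and 13 did not pass, with the most abundant, miR-9-5p, at 0.09 ± 0.03 (limma adjusted p = 0.156). Of 16 miRNAs of synaptic plasticity and activity, 3 fell (miR-138-5p, miR-485-5p and miR-92a-3p), and miR-191-5p stood at 0.03 ± 0.03. Of 21 miRNAs studied with addictive drugs, miR-339-3p (-0.30 ± 0.06) and miR-431-5p (-0.15 ± 0.03) fell, miR-30a-5p rose and 18 did not pass. These lists had camera adjusted p = 0.866, 0.807 and 0.958. Adjusted over the list alone, 3 neuron-enriched members fell, 4 synaptic members fell and 1 rose, and 2 members of the addictive drug list fell and 1 rose.

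No list of a family or cluster passed in camera. In the Dlk1-Dio3 cluster, 4 of 93 tested arms fell (miR-434-3p, miR-485-5p, miR-431-5p and miR-411-5p) and 89 did not pass (camera adjusted p = 0.958). In the miR-29 family, miR-29b-3p rose by 0.20 ± 0.04 while the most abundant member, miR-29a-3p, stood at -0.03 ± 0.03. The miR-30 family had 1 of 5 members higher (miR-30a-5p). In the miR-17-92 family clusters, miR-92a-3p fell by 0.12 ± 0.03 and miR-106b-5p rose by 0.14 ± 0.03, with 17 of 19 not passing; miR-92a-3p passed in 12 of 18 alternative settings. Adjusted over the list alone, 3 Dlk1-Dio3 arms were lower, and the counts of the other family and cluster lists were as over all miRNAs. None of the 9 let-7, 4 miR-181 and 19 Sfmbt2 cluster members passed, with let-7f-5p at 0.02 ± 0.04, let-7d-5p at -0.06 ± 0.03, miR-181b-5p at -0.06 ± 0.03, miR-467a-5p at -0.16 ± 0.08 and miR-467e-5p at -0.28 ± 0.10. The camera adjusted p of the miR-29, miR-30, let-7, miR-181, miR-17-92 and Sfmbt2 lists were 0.807, 0.865, 0.807, 0.776, 0.958 and 0.865. In 8 of the 17 lists the mean, the median and the direction of the test differed in sign, and none of these passed. Of the list members named, miR-150-5p, miR-431-5p, miR-411-5p and miR-106b-5p were chosen after their values were seen. fry's test for change in either direction, which does not compare a list with other miRNAs, passed for 13 of the 17 lists, among them the Dlk1-Dio3 (adjusted p = 0.000106) and miR-17-92 (adjusted p = 0.00313) lists.

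**Figure D4:**
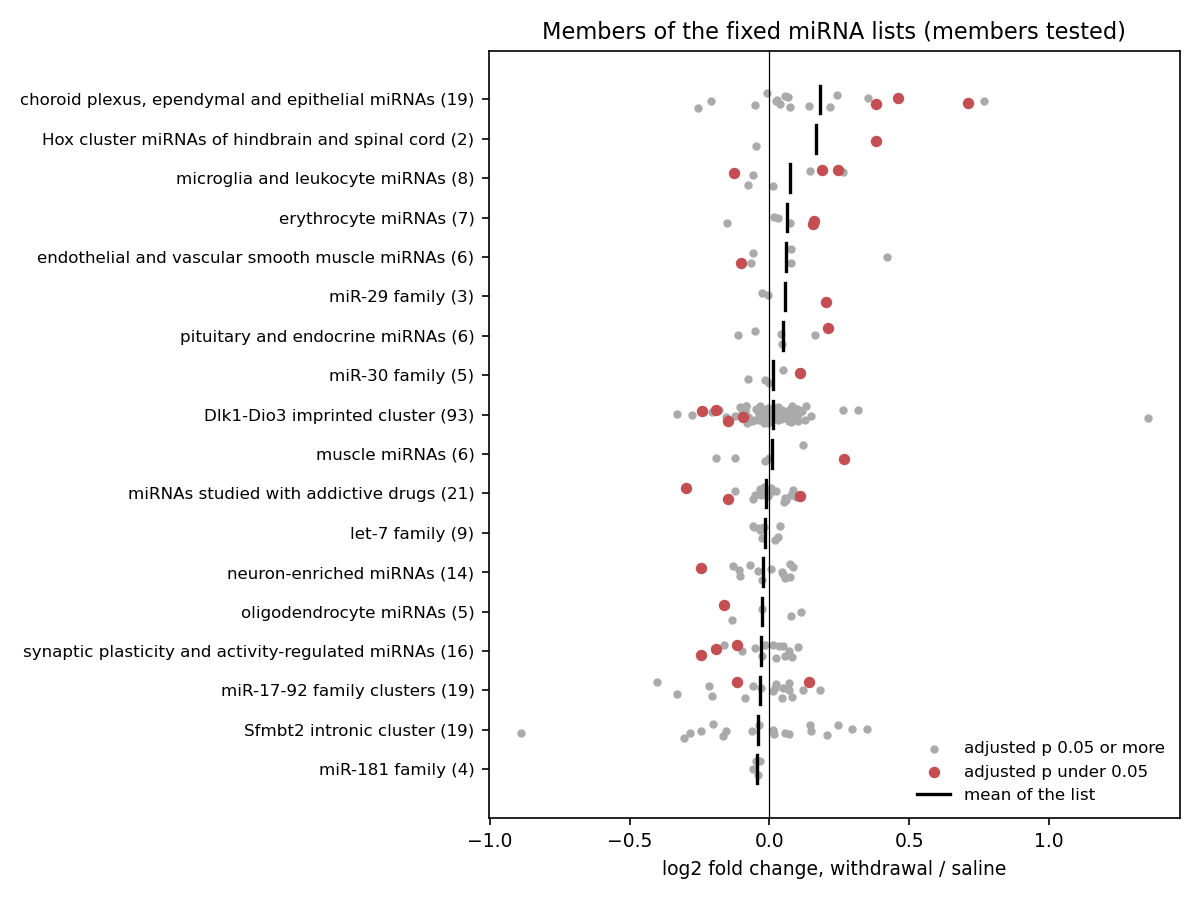
Log2 fold changes (withdrawal over saline) of the members of each list, with the number of tested members in parentheses. Points are miRNAs, red where adjusted p was under 0.05, and bars are list means; the highest mean is that of the choroid plexus, ependymal and epithelial list, 0.18.

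The balance between the 5p and 3p arms of a precursor, which shows whether one strand is favoured, was compared for 203 precursors. None passed in limma with Benjamini-Hochberg adjustment, where 33 had an unadjusted p under 0.05 and the smallest adjusted p was 0.129. This test had no trend of variance on level, and without that trend the miRNA test called 0 as well. In simulated data with 40 precursors changed in each run, it called 78.8% of those whose 5p arm was changed by 1.5-fold. Smaller shifts may be missed, and so may shifts of fewer precursors. The smallest p belonged to miR-431, whose log2 ratio of 5p to 3p fell by 0.23 ± 0.04 in withdrawal. It fell by 0.22 ± 0.04 for miR-485 and was 0.21 ± 0.05 higher for miR-324. Without withdrawal 3, 1 precursor passed, miR-6990 (limma adjusted p = 0.0303), which is named after its value was seen.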

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

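Equal library totals, quantile normalization, the filter on miRNAs above 0 in every library and the robust prior were chosen after seeing the data. The count of 46 miRNAs stayed between 42 and 48 under the other pseudocounts, filters, median-ratio rescaling, the robust prior and without the most abundant miRNA. It was 0 in limma without a trend (smallest adjusted p = 0.141), where the variance of each miRNA is no longer drawn toward that of miRNAs of its level. It was 61 with equal totals, which moved the median log2 fold change to 0.04, and 22 with quantile normalization, 13 of them among the 46, where the cause was not tested. Leaving out one library gave from 13 to 58. With the replicate number as a replicate block, 1.1e+02 passed (49 higher and 57 lower), all 46 among them. Same-numbered libraries deviated together with r = -0.07, 0.09 and 0.04, and 3 of 6 correlated best with their own number. Libraries of different numbers had r from -0.16 to 0.10. These values cannot decide whether the numbers mark pairs or batches, since the block raised the count, so this stays open. The count of lists stayed at 1 in each setting run for lists (all but the one without the most abundant miRNA) except the estimated correlation, where it was 0 (epithelial list mean 0.18, adjusted p = 0.290; range over its settings 0.000678 to 0.290). Arm ratios past the threshold ranged from 0 to 1 with one library left out, the 1 being without withdrawal 3, where the cause was not tested. For named miRNAs past the threshold, 400 values in the alternative settings stayed past it, 84 kept their direction below it and none reversed; quantile normalization moved miR-22-3p, miR-16-5p, miR-30a-5p and miR-486b-5p by over 1.5 times, to -0.06, -0.04, 0.06 and 0.09. Alternatives planned for raw counts were not run, since the table holds normalized values. Depth limits what can be called among low miRNAs: 1 of the 194 under 100 normalized reads passed, against 23 of the 157 of at least 10000.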

Other observations

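Of the 46 miRNAs past the threshold, 23 belonged to none of the fixed lists; those named here outside the rule were chosen after their values were seen. Among the higher ones, miR-598-3p stood at 28832 ± 270 normalized reads in controls and 32032 ± 1519 in withdrawal (n = 3 each), a log2 fold change of 0.15 ± 0.03. miR-100-5p rose by 0.12 ± 0.03, miR-384-5p by 0.14 ± 0.04 and miR-3068-5p by 0.21 ± 0.05. Among the lower ones, miR-877-5p fell from 1057 ± 27.2 to 836 ± 126 (-0.35 ± 0.09), miR-3061-3p by 0.29 ± 0.07, miR-153-5p by 0.15 ± 0.04 and miR-151-5p by 0.12 ± 0.03.

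The test of choroid plexus against other members, the tests on the miR-15/16 family, the splits for miRNAs and arm ratios and the second matching of neighbours were chosen only after the results were seen, as was the restriction of choroid plexus members by level. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For miRNAs past the threshold the real split gave 46 and the highest other 0, and 1 of the 10 splits gave as many. For lists the values were 1 and 0. For arm ratios they were 0 and 1, where all 10 splits give at least 0 by definition, so that comparison is void.

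The epithelial list was higher in withdrawal by 0.18 ± 0.03 (mean log2 fold change ± SE over libraries), a call that ended with an estimated correlation (adjusted p = 0.290). The 10 choroid plexus and ependymal members had a mean log2 fold change of 0.08 ± 0.03, below 0.29 ± 0.07 for the other 9. The difference was -0.22 ± 0.08 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). It was -0.21 ± 0.08 for the 8 below the level of the highest other member. This cannot decide whether more choroid plexus or ependymal tissue was the whole source. The split was made after the results were seen, and the 3 members past the threshold all lie among the other 9. Levels were also not matched between the parts. The list mean was 0.20 ± 0.04 with the estimated depth in the model and 0.18 ± 0.02 for the 15 members averaging at least 100. At its lowest it was 0.17 with a withdrawal library left out. These values argue against depth, low values or 1 library, for depth if a step is 1 read in each library. A response of striatal cells to the treatment and more choroid plexus or ependymal tissue both stay open. So does a difference in dissected tissue that carries miR-182, miR-183 and miR-200 family members.

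A candidate pattern among the lower miRNAs is the miR-15/16 family, whose 6 measured 5p arms share a seed and had a mean log2 fold change of -0.17 ± 0.03 with 4 past the threshold (-0.13 with equal library totals, -0.14 with quantile normalization, all 6 negative in each). Of 10000 random lists of 5p arms matched on level, 0 had a mean as low (95% range -0.08 to 0.08), but the family was picked from the calls, so this comparison cannot decide whether the pattern exceeds chance. Reads shared among members stay open too: miR-497a-5p and miR-15b-5p differed by -0.33 ± 0.11, but they are the extremes of the 6, picked after their values were seen, and miR-15a-5p and miR-16-5p were alike at -0.14 and -0.15. Less precursor RNA cannot be told apart from an effect on the mature 5p arm. The 3p arms had a mean of 0.032 ± 0.055, above the 5p mean by more than 2 standard errors. That was the bound first written against less precursor RNA. The 7 arms went both ways, though, with an SD of 0.22 between arms, which is not the error of the mean. miR-16-1-3p stood at 0.28 ± 0.08 and miR-15a-3p at 0.28 ± 0.14. miR-322-3p stood at -0.09 ± 0.05, miR-497a-3p at -0.36 ± 0.33, and the rest between 0.00 and 0.06. None of the 3p arms passed, and the pooled mean need not hold for each precursor. A slightly lower level of the family's 5p arms in withdrawal may be followed up as a hypothesis.

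Fold changes of neighbouring precursors were compared over pairs within 10 kb. The planned matching to a single precursor covered 559 of 699 miRNAs (79.97%, under the 80% needed), so its one-sided permutation p = 0.140 is void. Matching to any copy, chosen after that result was seen, covered 579 and gave a one-sided permutation p = 0.113 over 1098 pairs. Both arms of a precursor had a Spearman's rho of 0.067 over 203 precursors (one-sided permutation p = 0.169), and of 0.165 over the 77 whose arms both average at least 1000 (one-sided permutation p = 0.0771; precursors are not independent replicates). For the arms and for the planned matching, a value within the permutations was written beforehand as counting against a shared change, but a p that misses the threshold excludes nothing, so both questions stay open.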
